A study of Homo sapiens with 4 samples.

How the data were processed

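RNA of C4-2 cells, an established human prostate cancer line, was sequenced in 4 libraries: 2 of control cells and 2 of enzalutamide-resistant cells. Enzalutamide is an antiandrogen drug used against prostate cancer. The labels state that cells were cultured with or without the drug for 1 month, that total RNA was extracted and that libraries followed Illumina protocols. They do not say whether control cells were given vehicle. Culture with the drug goes with the resistant group, so in every result below an effect of the drug cannot be told apart from resistance. The growth protocol names RPMI medium with serum and then FGF-2 with an expansion medium, and which cells, if any, received FGF-2 is not clear from it. Whether poly(A) selection or rRNA depletion was used is not given in the sources used here.

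The authors deposited raw counts of reads per gene, 1 table per library, with no normalization. Reads were aligned with STAR 2.5.2b to GRCh38 (hg38) and counted with HTSeq, per the submitters' processing notes. The HTSeq version, its counting mode and strand setting, and the annotation release are not given in the sources used here. Reads that fit overlapping genes or several near-identical genes can therefore be missing or split, and values of antisense genes are uncertain. The same holds for UGT2B, AKR1C, HLA, histone and ribosomal protein genes, which have near-identical copies or pseudogenes. Each table ends in 5 rows that are not genes (no feature, ambiguous, low quality, not aligned, not unique). These were kept out of library sizes and tests. They held 74.4% and 71.08% of the HTSeq records of control replicates 1 and 2, and 55.41% and 56.87% of those of resistant replicates 1 and 2.

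Gene identifiers were matched without their version to GENCODE 29 (GRCh38) and a symbol table, which gave a symbol, type and position to 56753 of 60483 identifiers. Positions printed are from GENCODE 29. Gene counts summed to between 25589724 and 45033885 per library. Within a pair, counts differed by more than sampling noise, with a chi-square per degree of freedom of 5.67 over 22264 genes in the control pair and 2.38 over 24030 genes in the resistant pair, so each library counted as 1 replicate. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

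The comparison was resistant against control cells, fitted to all 4 libraries with group as the only term. Counts were filtered with filterByExpr at its default minimum count of 10, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the 20325 genes tested, and a gene was called at an adjusted p below 0.05. The fit had 2 residual degrees of freedom. The standard error of a log2 fold change is approximate, as its size divided by the square root of the F statistic. CPM values used TMM-scaled library sizes and are given as mean ± SD with n = 2. A gene without a count in a group was given a floor of 3 counts over the group. Such bounds cover counting error only.

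The design, the other settings to be tried, the rule for named genes and 32 gene lists were fixed before the data were examined. Lists were tested where at least 5 members passed the filter, with camera of limma 3.58.1 on log2 CPM (prior count 2) at the preset correlation of 0.01, adjusted over the 28 lists tested. Camera was repeated with an estimated correlation, and fry was run as another test. With an estimated correlation, the p of camera rests on the 2 residual degrees of freedom of the fit. Where the estimated correlation is above the preset one, a lost call can come from so few libraries as well as from correlated members. It does not tell these apart. Where the estimate is below the preset one, correlated members do not account for the loss. Lists covered androgen-induced, androgen-repressed and glucocorticoid-induced genes, androgen metabolism, neuroendocrine, luminal, basal or stem and mesenchymal genes. Others covered G1/S, G2/M, DNA repair, replication histones, cholesterol and fatty acid synthesis, endoplasmic reticulum stress and ATF4, hypoxia and glycolysis, respiratory chain, mitochondria-encoded and ribosomal protein genes. Signalling lists were interferon, NF-kB, immediate-early, growth factor, Wnt, p53 and NRF2 genes, with drug transport and autophagy and lysosome genes. Marker lists were fibroblast, endothelial, leukocyte and neural stem cells.

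Named genes followed a rule. NR3C1 and PGR were named whatever their values. The 10 largest rises and 10 largest falls were taken among called protein-coding genes with a mean log2 CPM of at least 3 and groups that did not overlap. From each list, the 2 called members with the smallest adjusted p could be named, with 4 from the androgen-induced list and 3 from the androgen-repressed, glucocorticoid-induced, androgen metabolism and neuroendocrine lists. Markers of other cell types were named where they reached 10 CPM in any library. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen.

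The other settings were DESeq2 size factors, total count and upper quartile scaling, no count filter, a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, glmTreat against 1.2-fold, the replicate number as a block, each library left out in turn, and mitochondria-encoded genes left out. Added after seeing the data were a correction for exon length and transcript GC content, as spline offsets per library with 5 degrees of freedom each, and counts thinned to a total of 25589724 per library. With 2 libraries per group, no count of other sample splits was made.

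The procedure was tested on simulated data, drawn for this comparison over 20325 genes with 200 changed. Of 50 genes at each size, 48% were called at 1.25-fold, 52% at 1.5-fold, 68% at 2-fold and 92% at 4-fold. Above 2 CPM the shares were 63.2%, 81.2%, 93.3% and 100%. Of unchanged genes, 0.0646% were called. In the data 13148 genes were called, so the Benjamini-Hochberg cutoff was stricter in the simulation, and these shares do not carry over to the data. The simulated changes had random signs, so they do not test the TMM scaling. A simulated length slope of 0.6 gave 0.603 before the correction and 0.0146 after it.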

Results

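The data were gene-level read counts from 2 control and 2 enzalutamide-resistant libraries of C4-2 cells. Gene counts totalled 25589724 and 29866008 in control replicates 1 and 2, and 45033885 and 39047453 in resistant replicates 1 and 2. Between 32700 and 35132 genes had a count. The groups differed in library makeup: reads not aligned were 35.56% ± 1.97 of HTSeq records in control and 20.49% ± 0.24 in resistant libraries (SD, n = 2). RN7SK, a small nuclear RNA chosen after its values were seen, took 11.35% ± 0.212 of gene counts in control and 6.595% ± 0.205 in resistant libraries. Log2 CPM correlated across genes at r = 0.993 in the control pair and 0.996 in the resistant pair, against 0.9599 to 0.9614 between groups. Genes are not independent replicates. The biological coefficient of variation, as edgeR names it, was 4.02%. This spread may be technical, as the labels do not say that replicates came from separate cultures.

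The comparison asked how gene expression differs between enzalutamide-resistant and control C4-2 cells. Of 20325 genes tested, 6705 were higher and 6443 lower in resistant cells, and 1541 and 2062 of these were at least 2-fold higher and lower. The largest rises were DAB1 (a reelin signalling adaptor, 158-fold), TNC (the matrix protein tenascin C, 94.4-fold), OPRK1 (the kappa opioid receptor, 78.9-fold) and GAB3 (48.8-fold). PIGR, the polymeric immunoglobulin receptor, rose from 17.98 ± 0.983 to 679.8 ± 3.9 CPM, with a log2 fold change of 5.24 (SE 0.0489, edgeR adjusted p = 8.33e-14). MATN2, HS3ST4, FOS, TENM2 and CD74 rose by log2 fold changes of 5.07, 4.76, 4.69, 4.17 and 4.11. The largest falls were AFF3 (165-fold), ST6GALNAC1 (a sialyltransferase, 30.1-fold), EPHA6 (an ephrin receptor, 14.7-fold) and KCNN2 (a potassium channel, 13.2-fold). RND3, ELOVL7, KCNH8, AZGP1 and MAP2 had log2 fold changes of -3.32, -2.87, -2.66, -2.54 and -2.52. RPL22L1, a paralog of a ribosomal protein, went from 1195 ± 1.3 to 204.2 ± 3.6 CPM (log2 fold change -2.55, SE 0.0344, edgeR adjusted p = 8.15e-13).

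The sizes for DAB1 and AFF3 rested on few counts in the lower group. DAB1 had 4 and 1 control counts, and its log2 fold change of 7.31 became 8.67 without control replicate 1 and 6.54 without control replicate 2. AFF3 had 3 and 9 resistant counts, and its value of -7.36 became -6.67 without resistant replicate 1 and -8.41 without resistant replicate 2. Scaling moved the split of calls: 51% of called genes were higher with TMM and 64.4% when libraries were scaled by total count, which shifted the median of all genes by 0.188 on the log2 scale. Fold changes are relative to the TMM scale.

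PGR, the progesterone receptor, on chromosome 11 at 101029624 to 101130524 (GRCh38), rose 12-fold from 6.289 ± 0.124 to 75.23 ± 0.0443 CPM (log2 fold change 3.58, SE 0.061, edgeR adjusted p = 3.88e-12). NR3C1, the glucocorticoid receptor, was low in both groups, at 1.54 ± 0.313 and 1.463 ± 0.0458 CPM, with a log2 fold change of -0.06 (SE 0.201, edgeR adjusted p = 0.815). Its sign turned under total count scaling (0.13), without a count filter (0.034) and without control replicate 1 (0.15).

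Androgen-induced genes went both ways. Of 33 tested, 10 were higher and 18 lower, with a median log2 fold change of -0.18 (camera adjusted p = 0.199, and adjusted p = 0.379 with an estimated correlation). With total count scaling the median was 0.00868, with 15 higher and 13 lower. With the length and GC correction the list was called lower, with 8 higher and 21 lower (median -0.31, camera adjusted p = 0.016), but not with an estimated correlation (adjusted p = 0.24). ACP3, prostatic acid phosphatase, rose from 44.76 ± 1.96 to 179.1 ± 4.58 CPM. AZGP1 fell 5.83-fold and the centromere gene CENPN fell 2.72-fold. The remaining genes of this paragraph were chosen after their values were seen. KLK3 (prostate-specific antigen) fell from 677.2 ± 20.3 to 482.3 ± 7.1 CPM (edgeR adjusted p = 1.86e-07) and TMPRSS2 rose from 103.6 ± 4.05 to 205.8 ± 0.632 CPM. FKBP5 fell from 53.35 ± 0.645 to 37.89 ± 0.669 CPM. KLK2 had a log2 fold change of -0.13 (edgeR adjusted p = 0.0181), which turned to 0.059 (adjusted p = 0.254) under total count scaling. TMEFF2 had 29 and 36 control counts and 0 in both resistant libraries, at least 37.4-fold lower, and the list's median is the same with this gene at its bound.

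All 10 androgen-repressed genes tested were called, 7 higher and 3 lower (median 0.41, camera adjusted p = 0.116, and adjusted p = 0.366 with an estimated correlation). OPRK1, on chromosome 8 at 53225716 to 53251697, rose from 0.2652 ± 0.0785 to 21.54 ± 0.239 CPM. UGT2B17, which glucuronidates androgens, had a log2 fold change of 1.78, or 2.39 with the length and GC correction, and shares sequence with other UGT2B genes. CCN3 rose 4.07-fold. Of 14 glucocorticoid-induced genes, 8 were higher and 3 lower (median 0.29, camera adjusted p = 0.11, and adjusted p = 0.468 with an estimated correlation). KLF9 and DUSP1 rose 2.03-fold and 2.05-fold, and MT1X fell 1.89-fold. Of 12 androgen metabolism genes, 4 were higher and 3 lower (median 0.041, camera adjusted p = 0.64, and adjusted p = 0.679 with an estimated correlation). HSD17B4 rose from 170.4 ± 2.53 to 467.2 ± 6.18 CPM. AKR1C3 rose but stayed low, from 0.1698 ± 0.0622 to 1.838 ± 0.0404 CPM, and CYP11A1 fell from 0.9037 ± 0.0322 to 0.1001 ± 0.00509 CPM.

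**Figure D1:**
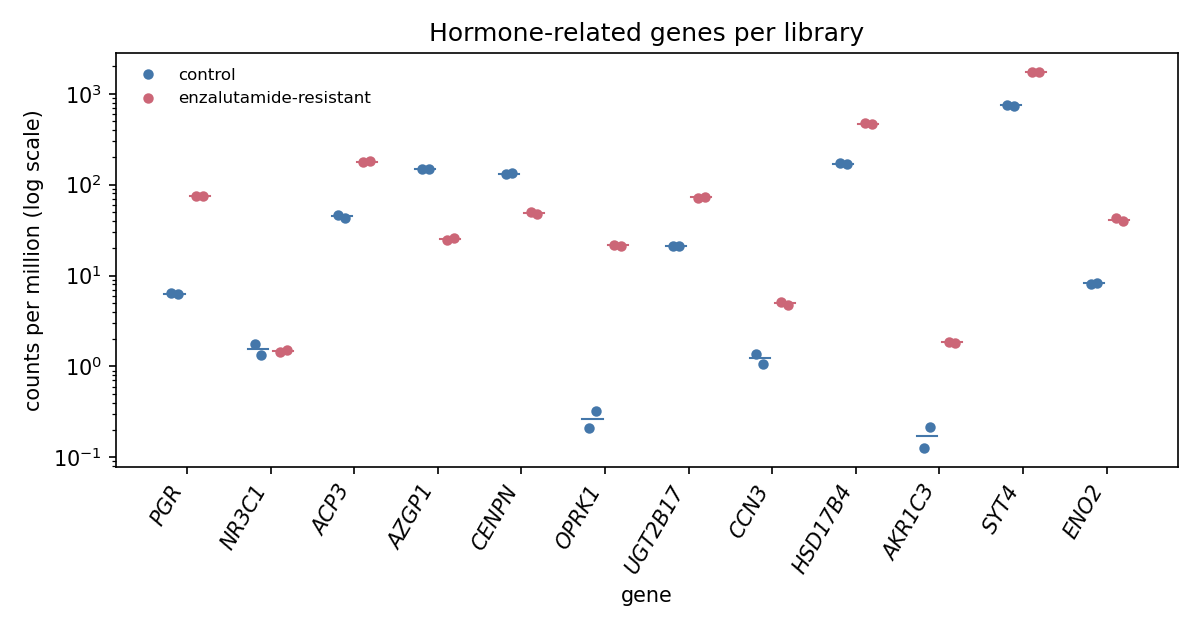
CPM (log scale) of hormone-related and neuroendocrine genes in each library, with 2 control and 2 resistant points per gene and a short line at each group mean. PGR sits at 6.289 CPM in control and 75.23 CPM in resistant cells, and NR3C1 at 1.54 and 1.463 CPM.

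Luminal genes were mostly higher in resistant cells. Of 17 tested, 13 were higher and 3 lower, with a median log2 fold change of 0.72 (camera adjusted p = 0.004, and adjusted p = 0.339 with an estimated correlation). Of 18 basal or stem genes, 8 passed the filter, and 5 were higher and 1 lower (median 1.12, camera adjusted p = 0.0247, and adjusted p = 0.339 with an estimated correlation). The call ended with the length and GC correction (median 0.87, camera adjusted p = 0.16). Keratins of this list were looked at after their values were seen. KRT5, KRT14, KRT17 and KRT6A did not pass, with at most 0.0839 CPM in any library, and the 1 lower gene was the keratin KRT15. ITGB4 and ITGA6, which form a laminin-binding integrin, rose 3.1-fold and 1.55-fold. Of 26 neuroendocrine genes, 11 passed the filter, and 3 were higher and 2 lower (median 0.21, camera adjusted p = 0.237, and adjusted p = 0.61 with an estimated correlation). With total count scaling 6 were higher and 2 lower (median 0.402), and with the length and GC correction 3 were higher and 3 lower, with the median turned to -0.076. SYT4, a synaptotagmin, rose from 745.1 ± 22.9 to 1738 ± 6.79 CPM and ENO2, neuronal enolase, rose from 8.185 ± 0.0663 to 41.25 ± 1.67 CPM. SYT1 reached 0.9267 ± 0.0201 CPM. Mesenchymal genes split 5 higher and 4 lower of 11 (camera adjusted p = 0.711, and adjusted p = 0.739 with an estimated correlation). Their median was -0.042, their mean 0.012 and the test's direction up, and the median was 0.146 under total count scaling and 0.080 with the length and GC correction. FN1, fibronectin, rose 1.49-fold. COL5A1 had a log2 fold change of 1.39, or 0.78 with the length and GC correction.

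Cell cycle genes were lower in resistant cells. Of 30 G2/M genes, 29 were lower and 1 higher, 13 of them at least 2-fold lower, with a median log2 fold change of -0.89 (camera adjusted p = 3.05e-09, and adjusted p = 0.274 with an estimated correlation). The median was -0.83 with the length and GC correction. CDK1, the mitotic kinase, went from 501.5 ± 7.52 to 128.6 ± 2.53 CPM and HMMR from 324.3 ± 12.2 to 91.03 ± 2.38 CPM. Of 28 G1/S genes, 23 were lower and 2 higher (median -0.44, camera adjusted p = 4.09e-05, and adjusted p = 0.274 with an estimated correlation). PCNA, the replication clamp, fell 2.79-fold and GINS1 fell 2.61-fold. Of 25 DNA repair genes, 18 were lower and 3 higher (median -0.36, camera adjusted p = 0.00261, and adjusted p = 0.379 with an estimated correlation). XRCC2 fell 2.74-fold, and RAD51AP1 had a log2 fold change of -1.86, or -1.24 with the length and GC correction. Of 15 replication histone genes, 14 were lower and the other 1 was not called (median -1.01, camera adjusted p = 5.49e-06, and adjusted p = 0.408 with an estimated correlation). H2AC11 and H1-5 fell 3.77-fold and 3.47-fold, with the limit that histone genes share reads with close copies. Small nuclear and nucleolar RNAs, which like most replication histone transcripts mostly lack a poly(A) tail, were looked at after the list results were seen. Of 69 snRNA genes tested, 38 were lower and 2 higher (median -0.78, or -0.228 with the length and GC correction). Of 142 snoRNA genes, 75 were lower and 21 higher (median -0.75, or -0.248 with the correction). Falls also outnumbered rises among antisense genes and processed pseudogenes, but their medians were not lower with the correction. Of 1831 antisense genes 590 were lower and 215 higher (median -0.289, or 0.0152 with the correction). Of 961 processed pseudogenes 303 were lower and 78 higher (median -0.372, or 0.0847). Medians stayed lower with the correction for processed transcripts (-0.215) and the type misc_RNA (-0.671). Of 13942 protein-coding genes 4378 were lower and 5902 higher.

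Genes of the respiratory chain and of the ribosome were lower. Of 30 respiratory chain genes, 24 were lower and 3 higher (median -0.79, camera adjusted p = 2.97e-06, and adjusted p = 0.339 with an estimated correlation). CYCS, cytochrome c, went from 850.6 ± 26.8 to 255.9 ± 1.07 CPM and NDUFA4 from 834.9 ± 36.4 to 241.9 ± 0.559 CPM. Of 30 ribosomal protein genes, 26 were lower and 1 higher (median -0.61, camera adjusted p = 8.69e-07, and adjusted p = 0.366 with an estimated correlation). RPS14 went from 2368 ± 92.8 to 746.5 ± 8.87 CPM and RPS24 from 2885 ± 4.72 to 1153 ± 7.95 CPM. For comparison, 104 protein-coding genes of under 1000 exonic bases and a mean log2 CPM above 2, which can include members of these lists, had a median log2 fold change of -0.76. It was -0.39 with the length and GC correction. With the length and GC correction the medians were -0.67 for the respiratory chain and -0.66 for ribosomal proteins. All 13 mitochondria-encoded genes were lower (median -0.66, camera adjusted p = 0.0047, and adjusted p = 0.581 with an estimated correlation), but with the correction the median was -0.058 and the adjusted p 0.507. MT-CO3 fell 1.83-fold and MT-CO2 fell 1.94-fold.

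Genes of lipid synthesis and of the stress and ATF4 list were also lower. Of 23 cholesterol synthesis genes, 15 were lower and 5 higher (median -0.23, camera adjusted p = 0.0341, and adjusted p = 0.362 with an estimated correlation). The call ended without control replicate 2 (adjusted p = 0.0502), resistant replicate 1 (0.064) or resistant replicate 2 (0.0572). STARD4, a sterol carrier, and INSIG1, a regulator of sterol sensing, fell 4.55-fold and 1.96-fold. Of 15 fatty acid synthesis genes, 11 were lower and 2 higher (median -0.29, camera adjusted p = 0.0208, and adjusted p = 0.339 with an estimated correlation). The elongase ELOVL7 fell 7.33-fold and malic enzyme ME1 fell 2.82-fold. Of 25 endoplasmic reticulum stress and ATF4 genes, 16 were lower and 1 higher (median -0.36, camera adjusted p = 0.00393, and adjusted p = 0.339 with an estimated correlation). ASNS, asparagine synthetase, went from 643.4 ± 0.785 to 217.9 ± 1.68 CPM, and PSPH, of serine synthesis, fell 2.67-fold. Of 26 hypoxia and glycolysis genes, 15 were lower and 8 higher (median -0.23, camera adjusted p = 0.11, and adjusted p = 0.607 with an estimated correlation). With the length and GC correction this list was called lower (median -0.47, camera adjusted p = 0.00463), but not with an estimated correlation (adjusted p = 0.41). LDHA, lactate dehydrogenase, and PDK1 fell 2.58-fold and 2.62-fold. Total count scaling made the splits of these lists more even, with 8 higher and 11 lower for cholesterol synthesis (median -0.042), and 4 and 7 for fatty acid synthesis (median -0.11). It gave 8 and 14 for the stress and ATF4 list (median -0.17), and 9 and 10 for hypoxia and glycolysis (median -0.046).

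Inflammatory genes were higher in resistant cells. Of 18 NF-kB genes, 16 were higher, 13 of them at least 2-fold, with a median log2 fold change of 1.42 (camera adjusted p = 2.97e-06, and adjusted p = 0.274 with an estimated correlation). The other 2 were not called. BIRC3, an apoptosis inhibitor, rose from 39.14 ± 1.18 to 182.7 ± 0.468 CPM. The chemokine CCL20 rose from 3.256 ± 0.334 to 35.26 ± 0.289 CPM, a log2 fold change of 3.43, or 4.24 with the length and GC correction. Of 34 interferon response genes, 26 were higher and 3 lower, 18 at least 2-fold higher (median 1.04, camera adjusted p = 4.5e-06, and adjusted p = 0.274 with an estimated correlation). The class I antigen gene HLA-B rose 3.47-fold, with reads that other HLA genes can share. Of 13 immediate-early genes, 10 were higher and the other 3 were not called (median 1.03, camera adjusted p = 0.000295, and adjusted p = 0.339 with an estimated correlation). FOS and JUNB, subunits of the transcription factor AP-1, rose 25.9-fold and 3.45-fold.

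Of 21 growth factor response genes, 15 were higher and 5 lower (median 0.88, camera adjusted p = 0.0209, and adjusted p = 0.339 with an estimated correlation). ERBB2, a receptor tyrosine kinase, rose 2.44-fold and DUSP5 rose 5.17-fold. Of 15 Wnt genes, 8 were higher and 2 lower (median 0.63, camera adjusted p = 0.0341, and adjusted p = 0.339 with an estimated correlation). The ligand WNT5A rose 5.8-fold and the receptor TNFRSF19 fell 3.38-fold. Of 22 autophagy and lysosome genes, 14 were higher and 3 lower (median 0.46, camera adjusted p = 0.00974, and adjusted p = 0.352 with an estimated correlation). LAMP1 and SQSTM1 rose 1.99-fold and 2.09-fold. With the length and GC correction these 3 calls ended, at adjusted p = 0.107, 0.332 and 0.114. Of 20 p53 target genes, 13 were higher and 3 lower (median 0.36, camera adjusted p = 0.0251, and adjusted p = 0.366 with an estimated correlation). XPC and GDF15 rose 1.85-fold and 1.8-fold. With a filter of 1 CPM the Wnt and p53 calls ended, at adjusted p = 0.0909 and 0.0623. Of 19 NRF2 genes, 7 were higher and 5 lower (median -0.016, mean 0.075, camera direction up at adjusted p = 0.791, and adjusted p = 0.882 with an estimated correlation). Under total count scaling 12 were higher and 2 lower, with a median of 0.173. SLC7A11, the cystine transporter, fell 1.88-fold. Of 11 drug transport genes, 2 were higher and 4 lower (median -0.43, camera adjusted p = 0.46, and adjusted p = 0.679 with an estimated correlation). The sterol exporter ABCG1 rose 2.39-fold and the drug exporter ABCG2 fell 2.55-fold.

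Over the 28 lists, 9 were called higher and 10 lower with the preset correlation, and 0 by camera with an estimated correlation, where 2 lists each way had an unadjusted p below 0.05. That test rests on 2 residual degrees of freedom, so its 0 calls do not show that correlated members caused the loss. The estimated correlation was below the preset 0.01 for the luminal, G1/S, fatty acid synthesis, interferon, NF-kB, Wnt and growth factor lists (-0.0564 to -0.0137). The losses of these lists thus go with the 2 residual degrees of freedom. Fry called 14 higher and 11 lower. Unlike camera, fry called androgen-induced (adjusted p = 0.000681) and hypoxia and glycolysis genes (0.0119) lower. It also called androgen-repressed (fry adjusted p = 0.00168), glucocorticoid-induced (0.0101), androgen metabolism (0.018), neuroendocrine (0.0153) and mesenchymal genes (0.0101) higher. The mitochondria-encoded list was not called by fry (adjusted p = 0.0709). Adjusted over the list alone, the counts of higher and lower members equalled those over all genes in every list except the glucocorticoid-induced list (9 higher, 3 lower) and the hypoxia and glycolysis list (8 higher, 16 lower).

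**Figure D2:**
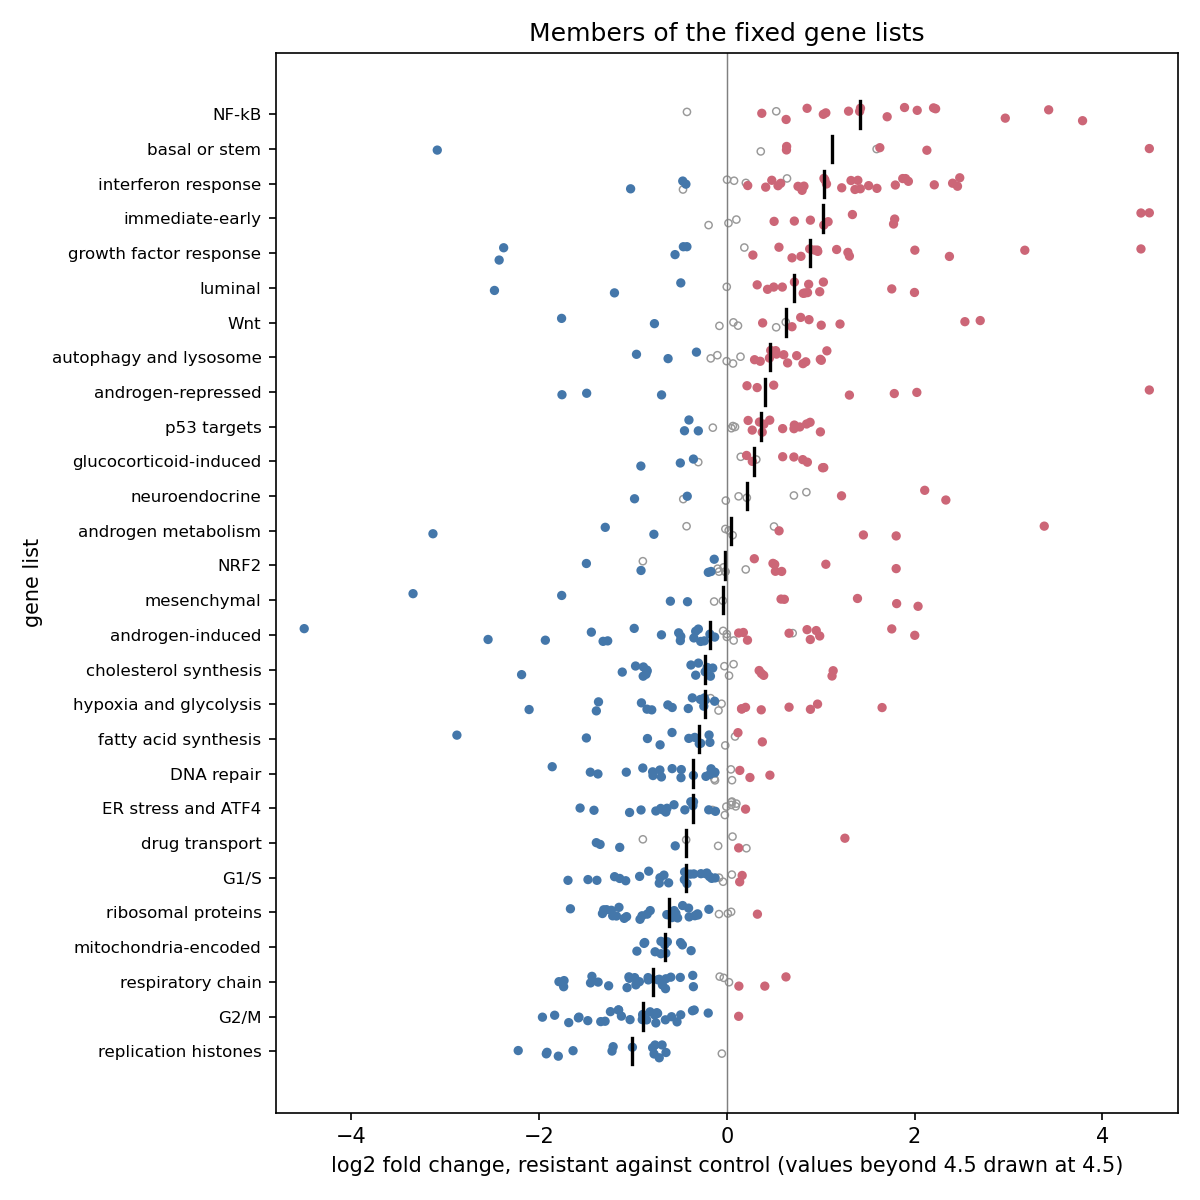
Log2 fold change of each tested member of the 28 lists, resistant against control, with values beyond 4.5 drawn at 4.5. Filled points were called higher (red) or lower (blue), open points were not called, and a black line marks each list's median, from 1.42 for NF-kB genes to -1.01 for replication histones.

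Markers of other cell types were scarce. Of 11 leukocyte markers, 2 passed the filter, and 0 were called by edgeR or by DESeq2 (also 0 at an unadjusted p below 0.05). With the length and GC correction 1 was called lower, CSF1R (chosen after its value was seen, -0.96, edgeR adjusted p = 0.0192), at 0.973 ± 0.166 CPM in control and 0.6158 ± 0.255 CPM in resistant cells. The 4 fibroblast markers tested gave 1 higher (COL3A1) and 1 lower (COL1A1), neither above 10 CPM in any library. COL1A1 had a log2 fold change of -0.42 (edgeR adjusted p = 0.00849), and its call ended without control replicate 2 (-0.23, adjusted p = 0.142). With the length and GC correction its value was -1.01 (adjusted p = 1.78e-06). COL3A1 had 0.61 (edgeR adjusted p = 0.0235), and its call ended without control replicate 1 (0.43, adjusted p = 0.121) or resistant replicate 1 (0.48, adjusted p = 0.112). It also ended with the length and GC correction (0.34, adjusted p = 0.18), the DESeq2 Wald test (adjusted p = 0.172), glmTreat (0.0625) and thinning (0.0696), and that of COL1A1 with total count scaling (adjusted p = 0.116), the DESeq2 Wald test (0.16) and glmTreat (0.0725). Of 4 endothelial markers, 3 were higher and 1 lower. EGFL7 alone reached 10 CPM and rose from 19.88 ± 1.42 to 35.86 ± 1.93 CPM. KDR had 0 and 1 control counts and 24 and 13 resistant counts, too few for a firm fold. Of 4 neural stem cell markers, 1 was lower, NES, at 3.106 ± 0.596 and 1.382 ± 0.0102 CPM.

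Fold changes followed gene length and GC content. Across 11979 genes with a mean log2 CPM above 2, which are not independent replicates, Spearman's rho of the log2 fold change was 0.224 with exon length and 0.296 with transcript GC content, and both explained 14.5% of its variance. Among the 10959 of these that are protein-coding, genes over 8000 exonic bases had a median of 0.26, against -0.76 under 1000 bases. With the correction, 6577 genes were higher and 6349 lower, 10200 of the 13148 calls were again called in the same direction and 436 were called in the opposite direction.

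**Figure D3:**
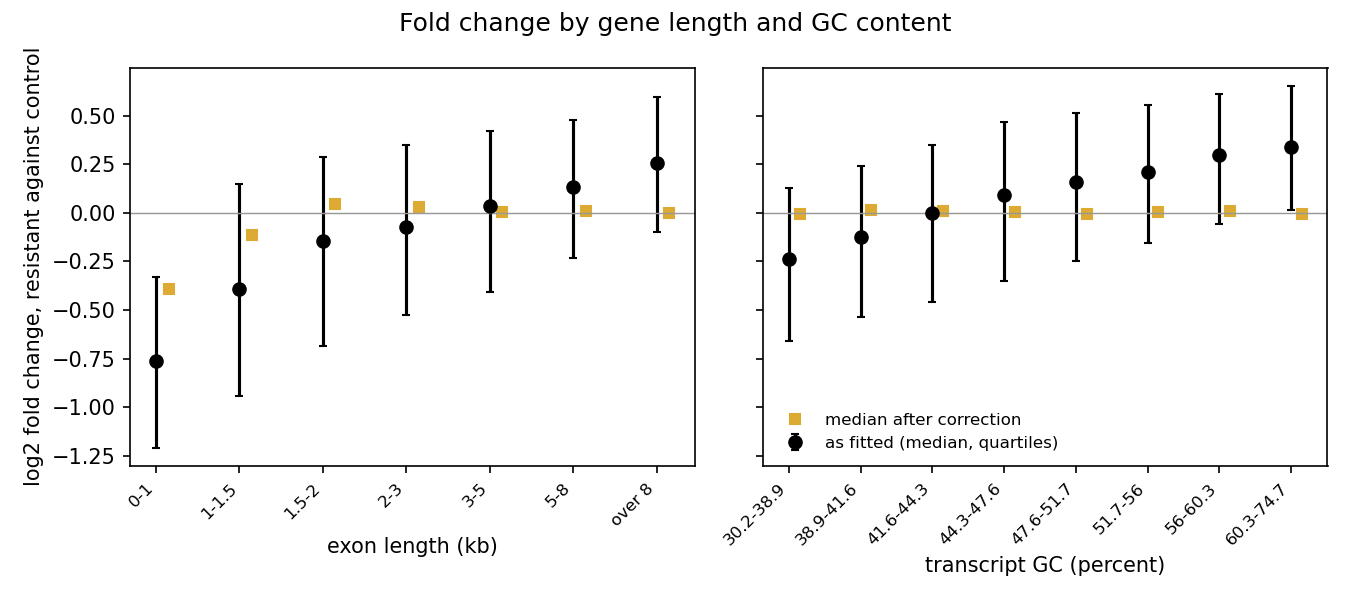
Log2 fold change, resistant against control, by exon length in kilobases and by transcript GC content in percent, for 10959 protein-coding genes, with black points at the median of each bin, bars from lower to upper quartile and yellow squares at the median after correction. The median runs from -0.76 to 0.26 over length bins and from -0.24 to 0.34 over GC bins, and the shortest bin stays at -0.39 after correction.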

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

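The tests of the length and GC correction on gene lists, the test of leukocyte markers and the gaps to matched genes per pair of libraries were chosen only after the list results were seen. Records that HTSeq assigned to no gene feature were higher in both resistant libraries than in both control libraries, at 8.168% ± 0.0891 against 6.043% ± 0.279 (SD, n = 2). Ambiguous records, also higher in both resistant than in both control libraries, were 3.843% ± 0.0983 in resistant and 3.316% ± 0.496 in control libraries. The direction depends on the denominator, since fewer records were unaligned in resistant libraries. As a percent of counted records, no-feature records were lower in resistant libraries (18.63% ± 0.236 against 22.21% ± 0.888), as were ambiguous ones (8.763% ± 0.0171 against 12.13% ± 0.774). Neither kind of record entered a comparison between groups, and neither difference was tested.

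Respiratory chain and ribosomal protein genes were lower, with a median log2 fold change of -0.726 over 60 members. The corrected median was -0.666. The correction did not take the whole trend out of short genes: protein-coding genes under 1000 exonic bases stayed at a median of -0.39, and those of 1000 to 1500 bases at -0.114. The corrected median of the lists lies below both, which argues against the length and GC trend as the whole cause only as far as the correction removes that trend. Random lists matched on length, GC content and mean expression had a median of -0.305, and 0.01% of 10000 were as low as the observed one, but they treat genes as independent. The 2 lists were also picked for their fall in these same data, so this share is not a chance rate. Both calls are lost with an estimated correlation (0.171 and 0.392, camera adjusted p = 0.339 and 0.366). With 2 residual degrees of freedom, that test cannot tell correlated members from too few libraries. The gap to the matched genes was -0.463 to -0.41 in the 4 pairs of a control and a resistant library, which reuse the same 4 libraries, against 0.0391 and -0.00971 between replicates. A bias that acts alike on genes matched in this way could account for part of the fall, but would not leave this gap. Gaps between replicates cannot bound a bias that goes with the groups. One that acts on these genes alone, such as reads lost to near-identical copies, is not covered by the matching. The different share of unaligned reads goes with the groups and stays open, as do culture with the drug and resistance.

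Interferon and NF-kB genes were higher, with both calls lost with an estimated correlation (camera adjusted p = 0.274 for each). The estimated correlations were -0.0292 and -0.0378, below the preset 0.01. The losses thus go with the 2 residual degrees of freedom of that test and not with correlated members, and do not decide the calls. Of 11 leukocyte markers, 0 reached 10 CPM in a resistant library, and the highest, CD68 (chosen after its value was seen), reached 1.11 CPM. This argues against leukocytes in the cultures. The corrected median of both lists was 1.15, which argues against the length and GC trend as the whole cause. A response of the resistant cells is a hypothesis drawn from these same data and was not tested. Culture with the drug goes with the resistant group, so a response to the drug cannot be told apart from resistance. Any other difference in how the cells were handled, for which the labels give nothing to test, may also raise these genes.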

How the results depend on the processing

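The length and GC correction and the thinning were added after seeing the data. For lists, an estimated correlation gave 0 called higher and 0 lower, fry 14 higher, and the length and GC correction 5 higher, against 9 and 10. The DESeq2 Wald test called 4101 genes lower and 1270 at least 2-fold lower, and the correction 1371 at least 2-fold lower, against 6443 and 2062. Every other count of genes was within 1.5 times its main value. The direction of the NRF2 list reversed under fry (adjusted p = 0.386), the 1 CPM filter (0.902) and the correction (0.929), and that of drug transport under fry (0.577). The log2 fold change of NR3C1 reversed under total count scaling (0.127) and no count filter (0.0342), and ranged from -0.2605 to 0.1508 with 1 library left out. The cause was not tested. Of 83 genes taken by the rule for named genes, 81 kept direction and call under the DESeq2 Wald test, 82 under the correction and 83 under voom. With 1 library left out, the remaining one is assumed to vary like the other group, and 11440 to 12974 genes were called.

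Replicate numbers shared no stated day or batch, and the replicate differences of the groups correlated at -0.0228 over genes, so the numbers do not pair the samples. With the replicate block, 13091 genes were called against 13148, and the cholesterol list was not called (adjusted p = 0.0691 against 0.0341).

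Thinned to equal total gene counts, which leaves TMM-scaled depth unequal, 12399 of 19075 genes were called (65%, against 64.7%). At the depth deposited, 52% of simulated 1.5-fold changes were called, and 81.2% of those above 2 CPM. With 200 of 20325 genes changed, the simulated cutoff was stricter than that of the data, so these shares do not give the recovery in the data.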

Other observations

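The test that leaves out gene clusters was chosen only after the window result was seen, and the gene families were chosen after their values were seen. Genes of HLA class II, which present antigens, were higher in resistant cells: 9 of 9 tested rose, with a median log2 fold change of 2.82, and 9 rose with total count scaling. HLA-DRA rose from 4.381 ± 0.204 to 31.02 ± 1.01 CPM (edgeR adjusted p = 7.57e-11) and HLA-DRB1 from 0.4057 ± 0.0194 to 8.663 ± 0.168 CPM, with reads that other HLA genes can share. CIITA, their transcriptional activator, had a log2 fold change of 0.89, or 0.354 and no call with the length and GC correction. Of 14 GALNT genes, which start mucin-type glycosylation, 10 were higher and 2 lower, with GALNT3 going from 51.38 ± 0.763 to 120.7 ± 1.31 CPM. Of 25 HOX genes, 19 were higher and 1 lower.

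Protocadherin beta genes were higher in 7 of 7 tested (median 1.77) and gamma genes in 18 of 19 (median 1.29), at low levels and with overlapping exons that make gamma counts uncertain. With the length and GC correction 7 beta genes (median 1.73) and 14 gamma genes (median 1.07) were higher. Of 78 mitochondrial ribosomal protein genes, 65 were lower and 2 higher (median -0.626). The split was 55 lower and 9 higher with total count scaling, and 61 lower and 8 higher with the correction (median -0.446). Among RNA types, 175 of 252 genes of the type misc_RNA were lower and 3 higher (median -1.05, or -0.671 with the correction).

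Neighbouring genes moved together more than shuffled genes did. The SD of the median corrected log2 fold change over 546 windows of 25 genes was 0.191, above the highest of 1000 shuffles of gene order, 0.1534. The window with the highest median, 1.16, lay on chromosome 5 at 141135218 to 141619055, from PCDHB5 to DIAPH1. Without 99 protocadherin, HLA and histone genes the SD was 0.181, above the highest shuffle of 0.1519, so these clusters alone do not give it. Regional copy number differences between the cultures may account for it, as a hypothesis. Shared regulation of neighbouring genes would give the same value, and no DNA data were analysed here.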
